A study of Mytilus galloprovincialis with 23 samples.

How the data were processed

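Poly-A selected, strand-specific RNA-seq libraries (TruSeq Stranded mRNA kit, per the labels' protocols) were made from the hepatopancreas, the digestive gland, of the Mediterranean mussel Mytilus galloprovincialis. The 23 libraries fall into 5 groups: untreated animals at day 0 (4 libraries), untreated animals at day 14 (4) and day 28 (5), and animals kept in 17α-ethinylestradiol (EE2), a synthetic estrogen, for 14 days (5) and 28 days (5). Groups were taken from the sample labels. The dose of 5 ng per l is the one in the series' design text, while the sample titles carry a unit of mg per l, so the dose is not settled by the labels. The day 14 samples are also labelled with 15 days. The labels speak of individuals but do not state that each library is a separate animal, so p-values measure only the spread between these samples, which may be technical.

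For each library the authors deposited a table of FPKM per gene, that is, fragments scaled to transcript length and to the fragments of that library, with a lower and an upper bound. STAR 2.50 and Cuffdiff 2.21 are named in the submitters' processing notes. The genome build is not given in the sources used here beyond the scaffold names (mg10_s followed by a number) and gene IDs (MGAL_10B followed by a number) of the tables. Per the file headers, the 2 tables of the whole series are the authors' own comparisons of EE2 with control at each time, 1 pooled FPKM per group and gene with the log2 fold change of EE2 over control, a test statistic (a score), and p-values and q-values as deposited. The authors' group FPKM were scaled between libraries by a method not given in the sources used here, and they are not the means of the deposited FPKM per library.

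Each library table held 60304 rows and 60302 gene IDs. The 2 IDs listed on 2 loci and 9 genes whose estimate had a status other than OK in some library were left out, which left 60291. Among the 9 were MGAL_10B092260 and MGAL_10B086664, listed at 0 in 20 and 17 libraries with the mark for too many fragments. For these genes a 0 is a failed estimate, so an FPKM of 0 is described below as listed at 0. None of the IDs matched the 43856 genes of the reference table at hand (assembly xbMytGall1.hap1.1; 0 matches), and the files do not pair the IDs with names. The 29 gene lists that had been fixed on gene names could therefore not be matched, and their tests were not run. Genes are given by ID, with the scaffold, start and end that the files print; whether the files count positions from 0 or 1 is not stated in them.

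Depth was estimated from the deposited FPKM bounds. Taking the upper bound as 2.0 standard deviations of a Poisson count above the FPKM gives an effective number of fragments per gene, which was whole within 0.02 for 53.6% to 64.2% of the values under 50 fragments. The total per library was taken as the 0.99 quantile, over genes with more than 50 fragments, of the total implied by fragments, FPKM and locus span. These numbers are estimates, not counts. A scale factor per library was computed from FPKM by the median of ratios to the geometric mean.

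The main test was limma 3.58.1 (R 4.3.3) on log2(FPKM + 1) with trended, robust empirical Bayes variances. It used the 19241 genes with an FPKM of at least 1 in at least 4 libraries, fitted the means of all 5 groups together, and adjusted p by the Benjamini-Hochberg method at a threshold of 0.05. A fold change on the log2(FPKM + 1) scale understates the change of genes at low FPKM. The 6 contrasts were EE2 against control at each time, the difference between these effects, and the 3 pairs of untreated groups. The design, the test, the alternatives and the rule for naming genes were fixed before the data were examined. By that rule, for IDs without names, at most 2 IDs that were higher and 2 that were lower are named per comparison, the largest changes first, among genes past the threshold whose groups do not overlap. For EE2 the list is filled by the smallest unadjusted p where fewer passed, and those genes are given as values. FPKM as deposited were not on one level between libraries, so results after quantile normalization of the log2 values are given beside them.

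The alternatives were limma without trend and robust variances, quantile normalization, a pseudocount of 0.1, no filter, an FPKM minimum of 5, fits on the compared groups only, the replicate number as a block, library quality weights, a minimum absolute log2 fold change of 1, and leaving out each library. Others were chosen after seeing the data: median of ratios scaling, quantile normalization with quality weights, the log2 scale factor as a covariate, leaving out the 7 libraries with a scale factor under 0.6, and limma's voom on the effective fragments. The fit was tested on simulated data with 50 changed genes per fold size. For EE2 at day 14, with 18054 genes, 2% of 2-fold, 16% of 4-fold, 34% of 8-fold and 56% of 16-fold changes were called, and 5 unchanged genes. The same simulation after quantile normalization gave 2%, 34%, 44% and 68%, and 8 unchanged genes. For EE2 at day 28, with 18102 genes, the shares were 0%, 2%, 6% and 38%, and with quantile normalization 4%, 30%, 36% and 54%. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1 was used for the rest, and matplotlib 3.10.9 for plots.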

Results

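Transcript levels were measured in the hepatopancreas of Mytilus galloprovincialis, the digestive gland in which mussels absorb nutrients and take up and transform pollutants. Animals were kept with or without 17α-ethinylestradiol (EE2), the estrogen of contraceptive pills that reaches coastal water with sewage. The dose is 5 ng per l in the series' design text, while the sample titles carry mg per l. There were 4 libraries of untreated animals at day 0, 4 of untreated and 5 of exposed animals at day 14, and 5 of each at day 28. The estimated total per library was 15.0 M fragments ± 5.89 (SD, n = 23; M for mega), with a range of 2.82 to 25.1 M. The smallest was control day 14 replicate 4. Spearman's correlation between libraries, across genes, had a median of 0.669 within groups and 0.648 between groups, and no 2 libraries held identical values.

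The genes with a listed FPKM held only part of these fragments, and that part differed between libraries. It was 14.6% ± 9.83 (SD, n = 4) at day 0, 27.4% ± 9.25 (n = 4) in controls at day 14, 30.6% ± 4.88 (n = 5) with EE2 at day 14, 24.7% ± 12.9 (n = 5) in controls at day 28 and 19.98% ± 8.68 (n = 5) with EE2 at day 28. The scale factor of FPKM, which is 1 where a library has the typical level of most genes, ran from 0.234 in control day 0 replicate 2 to 2.497 in control day 28 replicate 2. It was under 0.6 in 7 libraries: control day 0 replicates 1, 2 and 3, control day 28 replicates 4 and 5, and EE2 day 28 replicates 3 and 5. MGAL_10B074272 and MGAL_10B065741 together held 20.4% to 59.8% of the summed FPKM in those 7 libraries and 0.499% to 21.2% in the 16 others. MGAL_10B074272 had the highest FPKM of all genes in each of the 7 and in control day 14 replicate 1. In estimated fragments the 2 loci held at most 3.60% of a library.

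**Figure D1:**
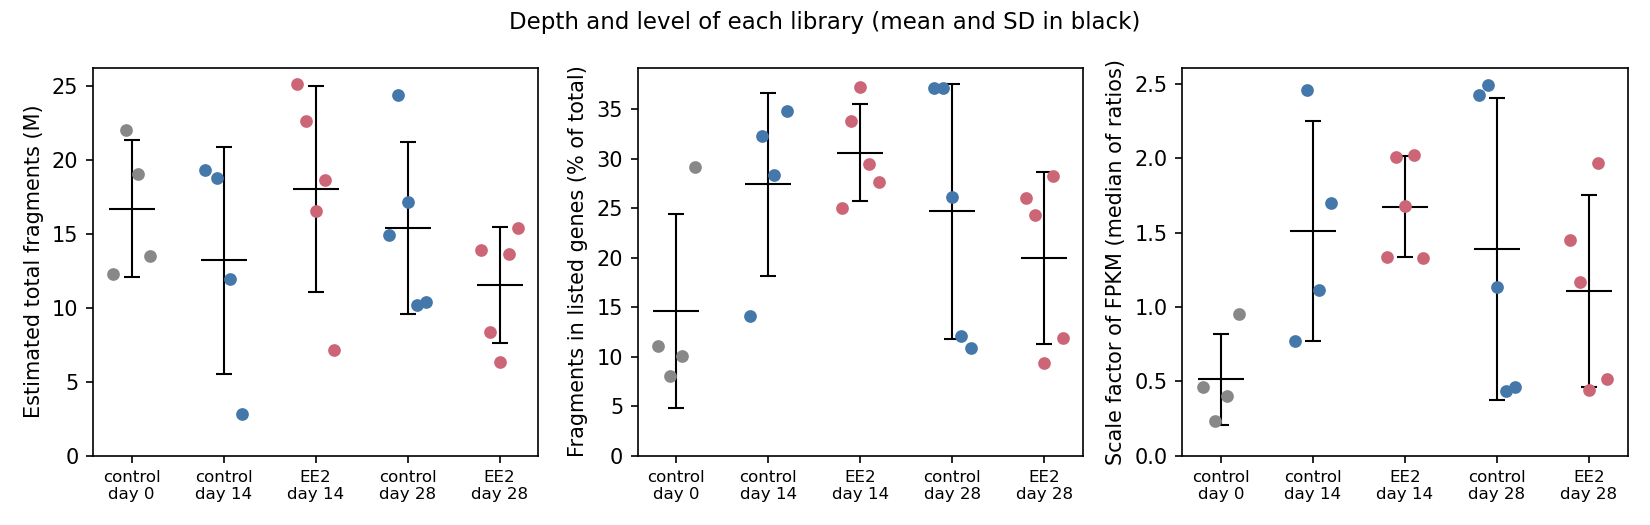
Estimated total fragments in M (left), percent of them in genes with a listed FPKM (middle) and scale factor of FPKM (right) per library, 1 point per library, with the mean and SD of each group in black. Control day 0 replicates 1, 2 and 3 had scale factors of 0.464, 0.234 and 0.402.

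The comparison at day 14 asked which genes of the hepatopancreas differed after 14 days in EE2. MGAL_10B084967, on scaffold mg10_s01217 from 163445 to 169707, rose with EE2. Its FPKM was 1.80 to 8.34 in the 5 exposed libraries (14.7 to 76 fragments), and in the controls it was listed at 0 in 3 libraries and at 0.978 in replicate 3. The log2 fold change was 2.21 ± 0.36 (SE; limma, adjusted p = 0.0168). MGAL_10B021325, on scaffold mg10_s03178 from 106373 to 120425, fell with EE2, from an FPKM of 8.64 ± 2.86 (SD, n = 4) to 0.793 ± 0.538 (SD, n = 5), a log2 fold change of -2.42 ± 0.35 (SE; limma, adjusted p = 0.00558). All 5 exposed libraries lay above the 4 controls for the first gene and below them for the second. The rule for naming genes required groups without overlap, so this is no further evidence. The second, MGAL_10B021325, was also low in untreated animals of the other days. Its FPKM was 0.517 ± 0.493 (SD, n = 4) at day 0 and 0.901 ± 1.19 (SD, n = 5) in the controls of day 28.

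The gene with the next smallest p among those higher with EE2, MGAL_10B090358 (scaffold mg10_s05402, 47340 to 65499), did not pass the test. Its FPKM was 1.91 to 4.75 with EE2 and 0 to 0.450 in controls, a log2 fold change of 1.61 ± 0.29 (SE; limma, adjusted p = 0.0665). MGAL_10B011330 was at 10.3 ± 4.02 (SD, n = 4) in controls and 0.696 ± 0.439 (SD, n = 5) with EE2, a log2 fold change of -2.72 ± 0.51 (SE; limma, adjusted p = 0.0788). No further gene passed at day 14, so the limma calls were 1 higher and 1 lower of 19241 genes tested.

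The calls at day 14 depended on the scaling between libraries. After quantile normalization 0 genes were higher and 3 lower, and none of the genes called as deposited was among them. MGAL_10B084967 then had a log2 fold change of 1.76 ± 0.34 (SE) and a limma adjusted p of 0.089, MGAL_10B021325 -2.36 ± 0.43 and 0.0635, and MGAL_10B011330 -2.63 ± 0.44 and 0.0388. With libraries left out in turn, the count after quantile normalization was 0 without control replicate 3 or any of EE2 replicates 1, 3, 4 and 5, 6 (all lower) without control replicate 1, and 2 higher and 0 lower without EE2 replicate 2. Over all alternatives the adjusted p ran from 0.00614 to 0.194 for MGAL_10B084967, from 0.00278 to 0.349 for MGAL_10B021325, and from 0.00723 to 0.784 for MGAL_10B011330. The call of MGAL_10B084967 was also lost without any of control replicates 1, 2 and 4 or EE2 replicates 1, 4 and 5, with limma adjusted p from 0.0653 to 0.152, and with the replicate number as a block (0.076). At an unadjusted limma p under 0.05 there were 669 higher and 220 lower genes as deposited, and 697 and 573 after quantile normalization. The median log2 fold change of all genes as deposited was 0.16.

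In the authors' deposited table for day 14, 53 of 22408 tested genes were called, 34 higher and 19 lower with EE2. MGAL_10B021325 was among them, with 29.0 FPKM in controls, 1.76 with EE2, a log2 fold change of -4.04 and a q of 0.0238 in the authors' deposited table. Of the calls in the authors' deposited table, 14 had the control group and 5 the EE2 group at 0. The limma fit tested 39 of the 53 genes of the authors' deposited table, and in all 39 the fold change had the same sign, both analyses resting on the same libraries. One of the 53, MGAL_10B021325, passed the limma threshold as deposited and 0 after quantile normalization. The scaled FPKM of the libraries did not overlap between the groups for 20 of the 53 genes of the authors' deposited table, against 2.81% of all genes tested and 1.59% by chance. The 53 were called on a difference between the same groups, so a larger share among them follows from the selection. In 6 of the 20 the control group of the authors' deposited table was at 0. For 28 of the 53 genes of the authors' deposited table a single library held over 50% of the summed scaled FPKM of the higher group.

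At day 28, MGAL_10B091834, on scaffold mg10_s02645 from 266 to 8766, was lower with EE2. It was listed at 0 in all 5 exposed libraries and at 4.99 to 18.1 FPKM in the 5 controls (73.6 to 210.2 fragments; limma, adjusted p = 1.81e-06), and no fold is given against a group at 0. MGAL_10B049445, on scaffold mg10_s03530 from 115697 to 129759, fell as well. Its FPKM was 2.00 to 6.41 in the controls and 0 to 0.595 with EE2, where 2 of 5 libraries listed it at 0, with a log2 fold change of -2.11 ± 0.26 (SE; limma, adjusted p = 0.000144). The other 2 genes that passed also fell, with log2 fold changes of -1.73 and -1.57 and limma adjusted p of 0.000144 and 0.0106.

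Both named genes that fell at day 28 were low outside the controls of that day. MGAL_10B091834 was listed at 0 in 9 of the 13 libraries of day 0 and day 14, and its highest value there was 3.03 FPKM, from 6 fragments, in control day 14 replicate 4. Over the whole series it was listed at 0 in 6 of the 11 libraries in which at least 20 fragments would be seen at its median level over the libraries that list it above 0. MGAL_10B049445 reached 1.09 FPKM at most in the libraries of day 0 and day 14. No gene was called higher with EE2 at day 28 as deposited. MGAL_10B034862 and MGAL_10B032845 had the smallest p in that direction, with log2 fold changes of 1.02 ± 0.27 and 0.91 ± 0.25 (SE; limma, adjusted p = 0.999 for both).

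**Figure D2:**
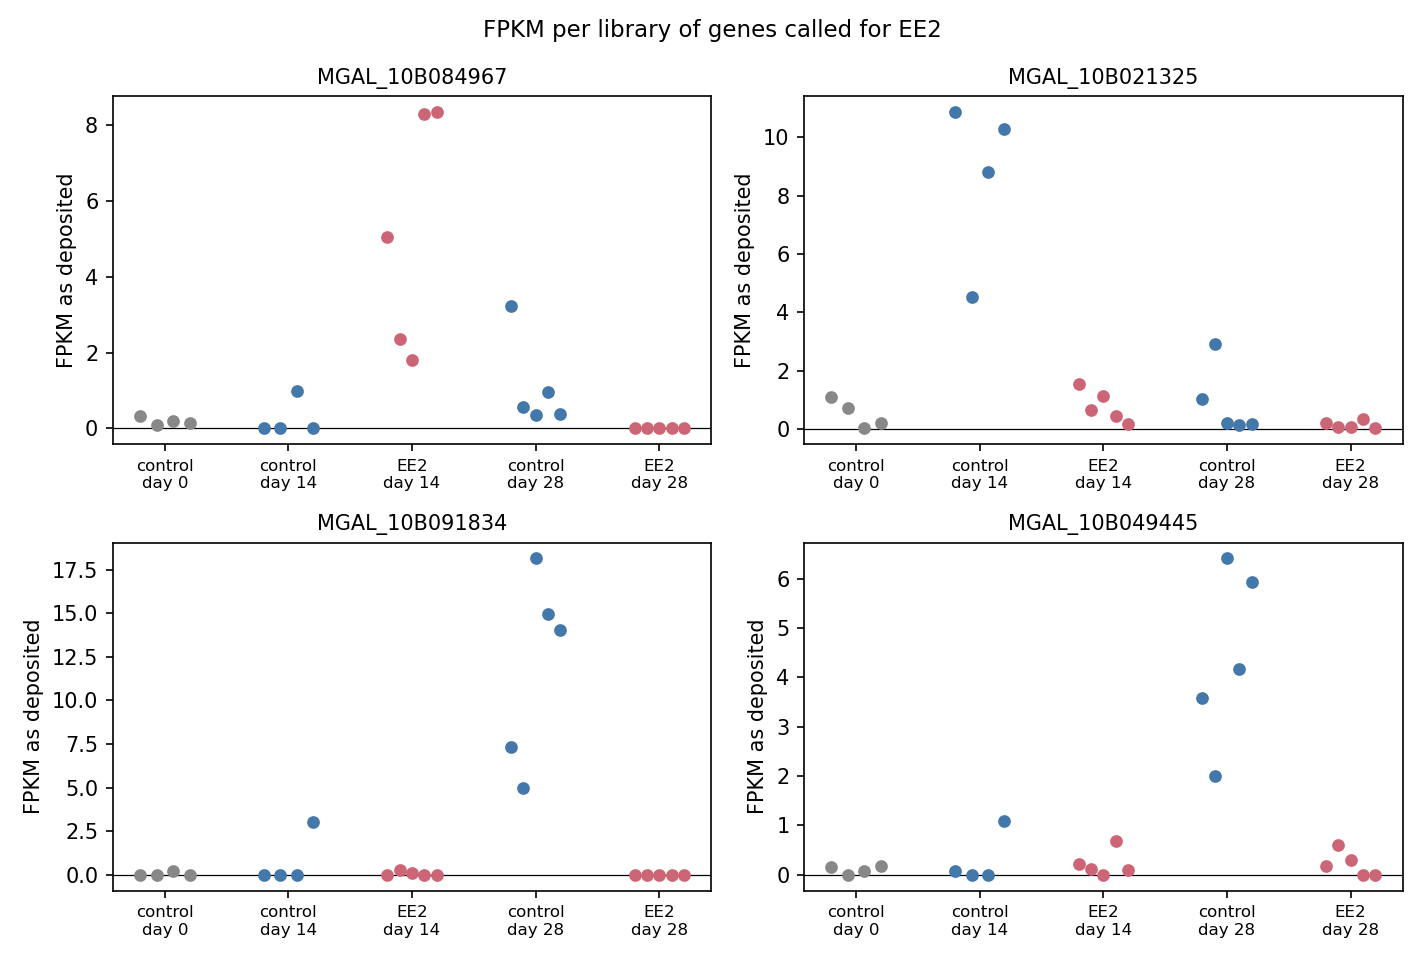
FPKM as deposited (vertical axis) of 4 genes called for EE2, 1 point per library, for the 5 groups on the horizontal axis. MGAL_10B021325 was at 4.54 to 10.9 FPKM in the controls of day 14, and MGAL_10B091834 at 4.99 to 18.1 FPKM in the controls of day 28, above all other libraries in both cases.

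After quantile normalization 2 genes were called lower and 0 higher at day 28, both among the 4 called as deposited. The limma adjusted p was then 0.00666 for MGAL_10B091834 and 0.160 for MGAL_10B049445, whose log2 fold change was -2.19 ± 0.42 (SE) in place of -2.11 ± 0.26. Without the 7 libraries with a scale factor under 0.6, a setting chosen after seeing the data, 2 genes were higher and 2 lower, with limma adjusted p of 0.0203 for MGAL_10B091834 and 0.177 for MGAL_10B049445. With quantile normalization of those libraries 1 gene was higher and 0 lower. Over all alternatives it ran from 3.54e-08 to 0.359 for MGAL_10B091834 and from 3.89e-06 to 0.830 for MGAL_10B049445. Unadjusted limma p under 0.05 were found for 108 higher and 214 lower genes as deposited, and for 336 and 458 after quantile normalization. Limma's voom on effective fragments called 0 genes. The authors' deposited table for day 28 called 0 of 19781 tested genes, with 485 genes at an unadjusted p under 0.05 and a smallest q of 0.0521. The median log2 fold change of all genes as deposited was -0.17.

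The difference between the EE2 effects at day 28 and day 14 was tested as an interaction. It passed for MGAL_10B091834 and MGAL_10B084967 (limma, adjusted p = 0.0107 for both), and the fitted effect of EE2 was lower at day 28 in both. MGAL_10B084967, which rose with EE2 at day 14, was listed at 0 in all 5 EE2 libraries of day 28 and at 0.342 to 3.23 FPKM in the 5 controls. MGAL_10B091834 was listed at 0 in 3 of the 4 control and 3 of the 5 EE2 libraries of day 14, so a fall with EE2 could hardly show there. The fitted differences on the log2(FPKM + 1) scale, which depend on the pseudocount where a group is at 0, were -3.15 ± 0.49 and -3.12 ± 0.49 (SE) as deposited, and -3.23 ± 0.76 and -2.65 ± 0.47 after quantile normalization. The limma adjusted p were then 0.487 and 0.113, with ranges over all alternatives of 4.24e-05 to 0.901 for MGAL_10B091834 and 0.00181 to 0.540 for MGAL_10B084967. Without control day 14 replicate 2 both calls were lost (limma adjusted p = 0.0569), and without replicate 3 that of MGAL_10B091834 (0.0596).

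No other gene passed the test of the difference, and 0 genes did after quantile normalization, where 0 to 2 passed with each library left out in turn. At an unadjusted limma p under 0.05 there were 163 higher and 745 lower differences as deposited and 588 and 745 after quantile normalization, and voom called 0. No gene was called for EE2 at both times. Across genes, which are not independent replicates, the log2 fold changes at day 14 and day 28 had a Pearson correlation of -0.155 as deposited and -0.121 after quantile normalization. Of 30 genes with an unadjusted p under 0.05 at both times, where independent lists give 14.9, 10 changed in the same direction. After quantile normalization these were 72 genes, against 52.4, and 23 in the same direction.

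Untreated animals at day 14 were compared with those at day 0. MGAL_10B073274 rose, from 1.32 to 29.3 FPKM in the 4 libraries of day 0 to 81.4 to 870 FPKM in the 4 of day 14, a log2 fold change of 5.43 ± 0.92 (SE; limma, adjusted p = 0.0237). MGAL_10B021325, which fell with EE2 at day 14, rose in the controls between day 0 and day 14, by a log2 fold change of 2.67 ± 0.37 (SE; limma, adjusted p = 0.00261). Its day 0 libraries lay between 0.0241 and 1.12 FPKM. One further gene was higher and no gene was lower. After quantile normalization MGAL_10B073274 had a log2 fold change of 4.08 and a limma adjusted p of 0.00713, and MGAL_10B021325 1.78 ± 0.45 (SE) and 0.069. Both its comparisons use the control libraries of day 14. The adjusted p ranged over all alternatives from 9.01e-05 to 0.858 for MGAL_10B073274 and from 9.01e-05 to 0.400 for MGAL_10B021325. The call of MGAL_10B073274 was lost without any of control day 0 replicates 1, 2 and 3 or control day 14 replicates 2, 3 and 4, with limma adjusted p from 0.0848 to 0.159, and with the replicate number as a block (0.0521).

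Between day 0 and day 14 the whole distribution shifted as deposited, with a median log2 fold change of 0.75. Genes with an unadjusted limma p under 0.05 numbered 5275, 99.01% of them higher. After quantile normalization there were 2718, 50.6% of them higher, and 50 genes were called higher and 80 lower. That count was 568 without control day 0 replicate 4 and 22 without control day 0 replicate 2. As deposited it was 108 without control day 14 replicate 1, in place of 3.

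At day 28, MGAL_10B091834 and MGAL_10B049445 were higher in untreated animals than at day 0. MGAL_10B091834 was listed at 0 in 3 of the 4 libraries of day 0, and its log2 fold change was 3.49 ± 0.36 (SE; limma, adjusted p = 9.17e-06). MGAL_10B049445 changed by 2.23 ± 0.28 (SE; limma, adjusted p = 0.000159). In all, 5 genes were called higher and 0 lower as deposited, and 16 and 27 after quantile normalization, where the 2 named genes had limma adjusted p of 0.0094 and 0.0353. Over all alternatives the adjusted p ran from 2.48e-10 to 0.427 for MGAL_10B091834 and from 2.37e-09 to 0.653 for MGAL_10B049445. The median log2 fold change as deposited was 0.61, and 98.2% of the 2788 genes with an unadjusted limma p under 0.05 were higher, against 47.0% of 2485 after quantile normalization. The count after quantile normalization was 703 without control day 0 replicate 4 and 9 without control day 0 replicate 2.

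All 4 genes called for EE2 at day 28 were among the 5 called between the untreated groups of day 28 and day 0, with the opposite sign. Both comparisons use the control libraries of day 28. In 100 simulations of unchanged groups, lists of these sizes with the smallest p shared 0.17 such genes on average and 1 at most, where independent lists would share 0.00104. The simulations drew the noise of each gene on its own, without the differences in level that the libraries share across genes. The chance overlap in the real libraries may thus be larger. With the 5 control libraries divided between the comparisons, the comparisons called 4 and 1 genes in one arrangement and 1 and 4 in the other, and shared 1 gene, the most these lists can share, in each. How much of the overlap comes from the shared controls is therefore open. Of the 4 genes called for EE2 at day 28, 3 were also called between the untreated groups of day 28 and day 14, with the opposite sign, against 0.19 on average and 2 at most in the simulations. For EE2 at day 14 and control day 14 against day 0, 1 gene was shared, MGAL_10B021325, which 14 of the 100 simulations gave as well. With the controls divided, one list was empty in one arrangement of each of these 2 pairs (4 and 0 calls; 0 and 659), so nothing could be shared. In the other arrangement 1 and 4 calls shared 1 gene, and 2 and 1 calls shared 0.

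**Figure D3:**
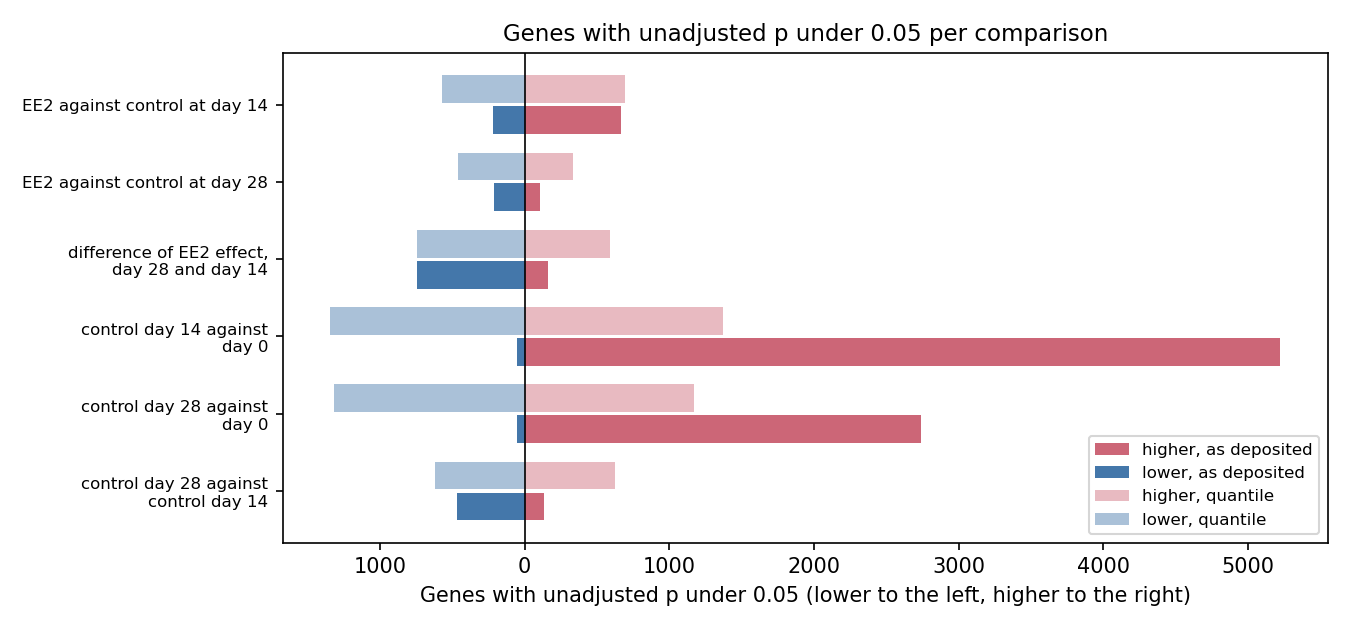
Number of genes with an unadjusted limma p under 0.05 (horizontal axis, lower to the left and higher to the right) in the 6 comparisons, as deposited (dark bars) and after quantile normalization (pale bars). For control day 14 against day 0 there were 5223 higher and 52 lower genes as deposited, and 1375 and 1343 after quantile normalization.

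Untreated animals at day 28 differed from those at day 14 in 4 genes. MGAL_10B091834 was higher at day 28 by a log2 fold change of 3.06 ± 0.36 and MGAL_10B049445 by 2.08 ± 0.28 (SE; limma, adjusted p = 0.000121 and 0.000816). MGAL_10B021325 was lower, at -2.46 ± 0.35 (SE; limma, adjusted p = 0.00135), with 0.145 to 2.92 FPKM in the controls of day 28. After quantile normalization the log2 fold changes were 3.26 ± 0.55, 2.31 ± 0.44 and -2.27 ± 0.43 (SE), the limma adjusted p 0.0405, 0.0647 and 0.0647, and 2 genes were called higher and 2 lower. That count was 0 without control day 14 replicate 3 or control day 28 replicate 4, and 17 without control day 28 replicate 2. Over all alternatives the highest adjusted p was 0.99 for all 3 genes, and the lowest 2.59e-07, 2.36e-05 and 5.35e-05. Genes with an unadjusted limma p under 0.05 numbered 135 higher and 468 lower as deposited, and 627 and 623 after quantile normalization.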

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

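The tests of explanations in this part were chosen after the results were seen, except the counts over other splits of the libraries, which were planned. Of 43 groups of values tested, 5 held a library far from the others, where chance gives about 1 group in 20 for values without ties. In 3 of the 5 all other libraries are listed at 0, which sets the gap over range to 1 for any value above 0, so the 5 are not set against chance.

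Control day 0 replicate 4 stood apart in the share of fragments in listed genes, at 29.2% against 8.01% to 11.1% in the other 3 libraries (gap over range 0.853). MGAL_10B084967 was listed at 0 in the controls of day 14 except replicate 3, with a gap over range of 1, and so was MGAL_10B091834 at day 0 except replicate 3 and at day 14 except replicate 4 (1 in each). For MGAL_10B049445, control day 14 replicate 4 stood apart with 1.09 FPKM (gap over range 0.914). That library is the shallowest, with 2.82 M estimated fragments, and its values rest on 6 and 5 fragments. The difference of the EE2 effect between day 28 and day 14 passed the test as deposited for MGAL_10B091834 and MGAL_10B084967. The limma adjusted p was 0.0107 (0.01068) for the difference itself in both, and 0.487 and 0.113 after quantile normalization. With MGAL_10B091834 mostly listed at 0 at day 14, a fall with EE2 could hardly show there.

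The first pattern is that the FPKM of most genes was lower in some libraries, most of all at day 0. Lower depth is argued against for day 0. Over the 1008 genes with at least 50 fragments in every library, the level at day 0 was still -1.46 on the log2 scale relative to later untreated libraries. Day 0 had 2.28 M more estimated fragments per library, not fewer (two-sided exact permutation p = 0.530 over 715 splits). The libraries of day 28 with a low scale factor were not covered. Control day 28 replicates 4 and 5 had 10.2 and 10.4 M, against 14.9 to 24.4 M in the other controls of that day. EE2 day 28 replicate 3 had 6.35 M, the lowest of its group, and replicate 5 had 15.4 M, the highest. The 2 listed loci with the highest FPKM are argued against as well: they held at most 3.60% (3.6) of the estimated fragments of a library, where loci would have to take a further 72.0% to lower the other genes by the gap between the median scale factors (1.56 in 16 libraries, 0.438 in 7). Loci without a listed value taking the fragments cannot be told. The log2 scale factor had r = 0.767 with the log2 share of fragments in listed genes over the 16 libraries. Both follow the level of the listed genes, so this is no independent evidence. The fragments of a locus are unknown for a library that gives it no value. The genes left out for a status other than OK had values in other libraries, which are not part of this share. Whether animals at day 0 differed from those held in the experiment, or their samples were handled apart, cannot be told apart, since day 0 is a single group (log2 scale factor -1.40 relative to the 9 later untreated libraries, two-sided exact permutation p = 0.0392). Neither would cover the low scale factors of control day 28 replicates 4 and 5 (0.431 and 0.463) and EE2 day 28 replicates 3 and 5 (0.438 and 0.516). Control day 0 replicate 4 was at 0.951.

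The second pattern is that genes called lower with EE2 stood out in the control group of that day: in 4 of the 5 such genes every control library lay above every other library of the series, exposed or not, in FPKM as deposited. The count is 3 on FPKM divided by the scale factor and 3 after quantile normalization. The 5 genes were called for controls above the EE2 group of the same day, so part of this follows from the selection. The filter adds to it: MGAL_10B005622 reached an FPKM of 1 only in the controls of day 28 (at most 0.687 elsewhere). Over all genes tested, every control library lay above every other library in 3 genes for day 28 and 7 for day 14, as deposited. Counting error is argued against at the mean level of the controls in FPKM divided by the scale factor. At that level the EE2 libraries of day 28 would hold 139.1 fragments on average for a called gene, and they held 1.83. The smallest expected number was 11.8, for MGAL_10B005622 in EE2 day 28 replicate 3, which held 1.1. For MGAL_10B091834 that level was raised by control day 28 replicates 4 and 5 (34.7 and 30.4), against 3.02 and 2.00 in replicates 1 and 2. A single library setting the difference at day 28 is argued against as well, since leaving out each library in turn left at least 3 called genes. Whether EE2 lowered these genes or something else raised them in that control group cannot be told apart: these counts (4 as deposited) go with either, the genes are near the floor in the other groups, and the labels name no tank or sampling time. MGAL_10B091834 is also one of the genes of the third pattern, so absence of the gene from the EE2 animals of day 28 stays open for it. No second control group of the same day exists in these data.

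The third pattern is 347 genes listed at 0 in at least 3 libraries in which at least 20 fragments would be seen at the gene's median level over the libraries that list it above 0, while at least 3 libraries held 20 or more. Counting error is argued against, with 1.32e-05 gene and library pairs at 0 expected among the 270171 judged over all 19292 genes and 4446 seen, of which the 347 genes hold 1756. That level leaves the zeros out, and 114 of the 347 genes have a median of 0 over all libraries. At the mean level over all libraries, zeros included, 3845 of 295851 pairs judged were at 0 and 1.35e-05 expected. Both expectations are this small because only pairs with at least 20 expected fragments were judged. They leave out the spread of a gene's level between animals, so they speak only to counting error at a fixed level. Of the 347, 293 were at 0 in one untreated library and present with at least 20 fragments in another. This argues against EE2 as the only switch for these 293 genes. It cannot decide whether EE2 also acts on some of them, and it does not cover the rest. Neighbouring genes of this kind on a scaffold (30 pairs, median gap 10728 bp) shared 0.436 of their absent libraries on average, against 0.281 for random pairs (one-sided permutation p = 0.0001, the smallest that 10000 draws can give). This is consistent with stretches of the genome absent from some animals, as a hypothesis, but 1 gene split into 2 models, copies too different from the reference to align, or joint regulation of neighbours would give it too. Of the 30 pairs, 2 had exactly the same absent libraries, and 498 judged values of these genes lay above 0 but under 0.1 of that median.

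Among the splits of the same libraries, the real one included, 18 of 100 gave at least the 2 genes of EE2 at day 14 (highest other 18), 5 of 100 the 4 genes at day 28 (highest other 10827), 8 of 100 the 2 genes of the difference (9518), 2 of 35 the 3 genes of control day 14 against day 0 (5993), 4 of 100 the 5 genes of control day 28 against day 0 (11134) and 12 of 100 the 4 genes of control day 28 against day 14 (9476). After quantile normalization, 5 of 100 splits, the real one included, gave at least 3 genes for EE2 at day 14 (highest other 4), 2 of 35 gave 130 for control day 14 against day 0 (2685) and 5 of 100 gave 43 for control day 28 against day 0 (4303). Such splits were not run after quantile normalization for EE2 at day 28, the difference and control day 28 against day 14. Only control day 28 against day 0 as deposited had a share under 0.05 (0.04), and none of the other 8 did. The shares were not adjusted for their number, and that comparison was at 0.05 after quantile normalization. Chance is therefore not excluded for any of them. The splits with the highest counts point to a structure of the samples: at day 28 the highest put all 4 libraries with a scale factor under 0.6 in one arm, and for control day 28 against day 0 all 5.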

How the results depend on the processing

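No value of a named gene changed direction under any setting run. Of 419 values of named genes under other settings, left-out libraries included, 307 kept their side of the threshold, 105 lost the call and 7 gained one. Of 90 counts under settings that keep every library of the main fit or leave out those with a low scale factor, 31 stayed within 1.5 times. Where a cause is not named, the cause was not tested. The main counts were 2 for EE2 at day 14, 4 at day 28, 2 for the difference, 3 for control day 14 against day 0, 5 for control day 28 against day 0 and 4 for control day 28 against day 14; counts below follow this order of comparisons and leave out those within 1.5 times unless the direction of the calls turned. The main calls against day 0 were all higher.

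Without trend and robust variances limma gave 1 gene for EE2 at day 14 and 12 for control day 14 against day 0. Quantile normalization gave 2 for EE2 at day 28, 0 for the difference, 130 for control day 14 (50 higher, 80 lower) and 43 for control day 28 (16 higher, 27 lower) against day 0. A pseudocount of 0.1 gave 1, 1, 1, 0, 2 and 1. No filter gave 1 for EE2 at day 14 and 0 for the difference, with 55611 genes tested. An FPKM minimum of 5, with 7122 genes tested, gave 0, 1, 0, 11, 0 and 0. Fits on the compared groups only gave 1 and 1 for EE2 and 0 for each of the 3 control comparisons. Library quality weights gave 4 for EE2 at day 14, 7 for the difference (1 higher, 6 lower), 9701 and 10268 for control day 14 and day 28 against day 0, and 13 for control day 28 against day 14.

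The settings of this paragraph were chosen after seeing the data. Median of ratios scaling, with the filter applied to scaled values and 17310 genes tested, so that scaling and gene set changed together, gave 0, 2, 0, 66 (23 higher, 43 lower) and 46 (14 higher, 32 lower) in the first 5 comparisons. Quantile normalization with quality weights gave 14, 2, 0, 1064 (449 higher, 615 lower) and 1984 (684 higher, 1300 lower). The scale factor as a covariate with quantile normalization gave 10 for EE2 at day 14, 25 for control day 28 against day 0 (12 higher, 13 lower) and 15 for control day 28 against day 14. Without the 7 libraries with a low scale factor there were 0 genes for EE2 at day 14, the difference and all 3 control comparisons, and 4 at day 28, of which 2 were higher and 2 lower with EE2. Day 0 then has 1 library, so against day 0 the spread comes only from the other groups, and these counts test a single sample. The same libraries with quantile normalization gave 0 for EE2 at day 14, 1 at day 28 (higher with EE2), 3 for the difference (all higher, where the main 2 were lower), 4 for control day 14 (all lower, where the main 3 were higher) and 3 for control day 28 (all lower, where the main 5 were higher) against day 0, and 0 for control day 28 against day 14. Voom on effective fragments, with 23252 genes tested, gave 1, 0, 0, 8 (2 higher, 6 lower), 12 (1 higher, 11 lower) and 0.

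Leaving out each library in turn gave 1 to 7 genes for EE2 at day 14 (7 without EE2 replicate 2), 3 to 5 at day 28, 0 to 4 for the difference (0 without control day 14 replicate 2, 4 without replicate 4), 1 to 108 for control day 14 against day 0 (108 without control day 14 replicate 1, 16 without control day 0 replicate 4), 3 to 8 for control day 28 against day 0 (8 without control day 28 replicate 5) and 4 to 8 for control day 28 against day 14 (8 without control day 28 replicate 2). After quantile normalization the ranges were 0 to 6, 2 to 4, 0 to 2, 22 to 568, 9 to 703 and 0 to 17. The replicate numbers showed no sign of pairing the samples. Over 43 pairs with the same number, deviations from the group means had correlations from -0.276 to 0.304 with a median of -0.032. Pairs with different numbers had a median of -0.011, and 2 libraries correlated best with their own number. Weak correlations cannot exclude a pairing behind the numbers. With the replicate number as a block 1 gene was called for EE2 at day 14, and the other counts did not change, but 2 of the 3 genes of control day 14 against day 0 were the same. MGAL_10B084967 lost its call at day 14 (limma adjusted p = 0.076, range over all alternatives 0.00614 to 0.194), and so did MGAL_10B073274 for control day 14 against day 0 (0.0521, range 9.01e-05 to 0.858). The tests of the 29 gene lists, and their alternatives, were not run because no gene ID could be matched to a name. Depth limits the low genes: listed genes held 0.595 to 9.07 M estimated fragments per library.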

Other observations

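Genes were also counted whose libraries of one group all lay above, or all below, every other library. After quantile normalization 25 genes lay above and 31 below at day 0, 17 and 8 in the controls of day 14, 3 and 6 with EE2 at day 14, 3 and 0 in the controls of day 28, and 1 and 1 with EE2 at day 28. Of 100 random sets of libraries of the same size, 0 had as many such genes in total as day 0, 4 as the controls of day 14, 1 as EE2 at day 14, 13 as the controls of day 28 and 23 as EE2 at day 28. As deposited the counts were 6 and 101 at day 0, 7 and 0 in the controls of day 14, 6 and 0 with EE2 at day 14, 3 and 0 in the controls of day 28, and 0 and 0 with EE2 at day 28, and 0, 6, 1, 3 and 100 of the 100 random sets had as many, so the standing of the controls of day 28 depends on the scaling.

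The 5 genes called higher in the controls of day 28 than at day 0 lie on 5 scaffolds. Besides the 2 named ones they include MGAL_10B005622, named after its values were seen, at 1.74 to 3.54 FPKM in the controls of day 28 and at most 0.687 in every other library. In FPKM as deposited, MGAL_10B091834 was at 15.0 and 14.1 in control day 28 replicates 4 and 5, the 2 controls of that day with a low scale factor. Divided by the scale factor, its FPKM was 34.676 and 30.373 in these 2 libraries. In replicates 1 and 2 it was 3.0198 and 1.9999, and replicate 3 lay in between. Relative to most genes, MGAL_10B091834 was thus higher in replicates 4 and 5 than in the other controls of day 28.

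Of the 300 genes with the largest limma statistics for EE2 at day 28 after quantile normalization, 182 were lower with EE2, and in 62.1% of these the control group lay farther from the mean of the other 3 groups than the EE2 group did. Among the 118 higher genes that share was 26.3%. At day 14 the shares were 74.2% of 132 lower and 55.4% of 168 higher genes. These genes were picked by the same difference between EE2 and control, and no share over all genes was computed. The shares therefore have no chance level beside them, and no conclusion about either group is drawn from them.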
